A study of Rattus norvegicus with 16 samples.

How the data were processed

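The study used male Sprague-Dawley rats that received a fluid percussion injury of the brain (TBI) or sham surgery and were tested for learning before tissue was taken at 1 week. RNA-seq libraries were made from about 1000 ng of total RNA by poly-A selection and random priming, from the hippocampal CA1 field and from white blood cells (WBC). The 16 libraries fall into 4 groups of 4. The labels number the samples of each group but do not say that equal numbers in the tissues are 1 rat, so samples were not paired, and the p-values measure only the spread between these samples.

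The deposited values are FPKM, in 1 table per tissue. Per the labels, the authors aligned with TopHat and TopHat2 over Bowtie and Bowtie2 to the rat build rn5 and computed FPKM with Cufflinks and Cuffdiff; versions, the annotation and the normalization setting are not given in the sources used here. Each deposited FPKM comes with a status from the authors' tool (OK, FAIL or HIDATA, the last for a locus with too many fragments to process). There are 26031 rows for CA1 and 24779 for WBC, of which 8207 and 7054 name no gene and 310 and 309 name several. The named rows hold 16405 and 16395 different symbols. No positions are reported, because the reference at hand belongs to another build than rn5, and only gene spans were taken from it, for lists matched on span. Symbols are as the files give them. FPKM gives no fragment counts, so the depth is unknown and no counting interval or detection limit is given. Depth relative to sham 1 was estimated from the spacing of the smallest FPKM values where that was clear, with sham 1 itself counted at 1. It was 0.853 to 1 in 4 CA1 libraries. In 6 WBC libraries it was 1, 0.80 and 1.01 in sham 1, 2 and 3, and 0.906, 1.34 and 1.37 in TBI 1, 2 and 4. The value of WBC TBI 1 rests on 23 rows.

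Values were taken as log2 of FPKM + 0.5. Rows were tested if their mean over the 8 libraries of the tissue was at least 1 FPKM and every status was OK, which left out 96 CA1 and 15 WBC rows above that mean. TBI was compared with sham within each tissue by limma 3.58.1 (lmFit and eBayes with a trend, 2-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. The effect of TBI was compared between tissues by the interaction term of 1 model over 7570 genes measured in both, where the tables, normalized separately, each have their own mean. Gene lists for cell types and pathways, the named-gene rule and the alternatives below were fixed before the data were examined. Lists with at least 5 tested genes went to camera, which compares a list with all other genes at a preset correlation between genes of 0.01. Camera with an estimated correlation, and fry, were run beside it, and the mean score of each list was compared by an exact permutation test over the libraries. Counts adjusted over the list alone use the limma p-values of the list's members.

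Named genes are, per tissue, the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap, filled up to 10 per direction by the smallest p and then reported as not passed. To these come the 3 members with the smallest p in the direction of each called list, and 10 genes per tissue named in advance. A gene that this rule names is not reported here, though the tests and lists include it. Between tissues up to 5 genes per direction were taken by adjusted p. Where rows share a symbol the row with the highest mean stands for the gene. XLOC_003441, the genes that passed adjusted over a list alone, and Tgm2 lie outside that rule and were chosen after their values were seen.

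On simulated normal values with each row's own mean and spread, in which 200 rows were changed, limma recovered 28, 58, 90 and 98% of log2 changes of 0.3, 0.5, 1 and 2 in CA1 and 2, 20, 64 and 94% in WBC. For the interaction term these shares were 2, 28, 80 and 100%. It also called 6, 7 and 8 rows that had not been changed, in CA1, WBC and the interaction.

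The alternatives tried were pseudocounts of 0.1 and 1, no filter or a minimum mean of 5 FPKM, median-ratio and quantile normalization, limma without the trend, with robust variances or with sample weights, samples with equal numbers as a block (sham with TBI, or CA1 with WBC), an adjusted p of 0.1, and leaving out each library. Added after the data were seen were rows of every status, rows with 1 symbol only, the WBC erythroid score as a covariate, and the lists compared between tissues. All distinct splits of the 8 libraries of a tissue into groups of 4 (35), or 100 drawn regroupings of both tissues, the real one included, were put through the same tests. Software was R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.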

Results

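The study asked how traumatic brain injury changes transcription in the rat hippocampus and in the blood. Poly-A RNA was sequenced from the CA1 field of the hippocampus, a layer rich in pyramidal neurons, and from white blood cells (WBC), 1 week after fluid percussion injury (TBI) or sham surgery. There were 4 libraries in each of the 4 groups (CA1 sham, CA1 TBI, WBC sham and WBC TBI), 16 in all. The values are FPKM, fragments scaled to transcript length and to the size of the library, so the number of fragments behind each library is unknown. How library size was set is not given in the sources used here. Summed over all rows, FPKM ran from 1726840 (TBI 4) to 3520670 (sham 2) in CA1 and from 482286 (TBI 1) to 832725 in WBC. The 10 highest rows held 69.0 to 82.8% of the CA1 sums and 18.6 to 35.8% of the WBC sums. Pearson's r between libraries, across rows on the log2 scale, was 0.967 to 0.981 in CA1 and 0.910 to 0.968 in WBC. On the first principal component of the WBC libraries, which carried 31.1% of the variance, TBI 1 lay at 57.0, the other TBI libraries at 4.36 to 19.1 and the sham libraries at -32.9 to -13.3. In CA1 that component (22.9%) set sham 1 (-27.4) and TBI 1 (-28.4) apart from the other 6 libraries (1.77 to 19.4). Fold changes are TBI minus sham on the log2 scale, with n = 4 libraries per group.

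CA1, TBI against sham: which genes of the injured hippocampus differ 1 week after injury. The only row to pass in limma, of 14637 tested, was an unnamed locus, XLOC_003441, at 9.11 to 10.8 FPKM in the TBI libraries. It was listed at 0 in 3 sham libraries and at 0.00348 FPKM in sham 3 (adjusted p = 9.11e-08). With rows of 1 symbol only, which leaves that locus out, 1 row passed higher and 1 lower. At the main settings no named gene passed. The nearest were Ppia (cyclophilin A, a peptidyl-prolyl isomerase), at 1.47 ± 0.12 FPKM (SD, n = 4) in sham and 2.91 ± 0.157 in TBI (limma adjusted p = 0.0569), and Cd93, an endothelial lectin-like receptor, at 2.23 ± 0.280 and 0.902 ± 0.0994 (limma adjusted p = 0.0746). Ppia has many near-identical copies in the genome, so its fragments are assigned with less certainty. Its row lies near the filter of 1 FPKM and may not give the level of the gene. The log2 differences were 0.79 ± 0.08 (SE) for Ppia and -0.96 ± 0.11 for Cd93, and in both genes all 4 TBI libraries lay on one side of all 4 sham libraries.

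The other CA1 genes with the smallest p in each direction, none of which passed (limma adjusted p = 0.710 to 0.891), also had fully separated groups. Those higher in TBI were the calcium sensor Hpcal1 (20.5 to 36.4 FPKM, log2 0.79), the nuclear receptor Nr2f2 (12.9 to 19.3, log2 0.56), Plagl1 (0.59), Wisp2 (0.69), Prokr2 (0.42), Pdzd2 (0.38), the collagen prolyl hydroxylase P4ha2 (0.32), the endoplasmic reticulum stress gene Herpud1 (0.21) and the clock output factor Dbp (66.8 ± 11.2 to 97.9 ± 8.22 FPKM, log2 0.56). Those lower in TBI were retinol saturase, Retsat (42.2 ± 6.09 to 21.3 ± 8.08 FPKM, log2 -1.03), the phagocytic receptor Megf10 (-0.49), Elk3 (-0.42), the urea transporter Slc14a1 (22.4 to 16.8, -0.40), the insulin-signalling kinase Akt2 (19.6 to 15.4, -0.34), the vascular growth factor receptor Flt1 (10.7 to 8.56, -0.30), Lpcat3 (-0.30), the thyroid hormone transporter Slco1c1 (35.9 to 29.5, -0.28) and the signalling scaffold Git1 (186 to 155, -0.26). At an unadjusted p under 0.05 limma gave 372 rows higher and 380 lower, 752 in all against 732 expected by chance. The groups did not overlap in 2.88% of rows, where chance gives 2.86%. The 752 became 1802 without sham 1 and 493 without sham 3, and the count of calls became 2 higher without sham 1, TBI 1 or TBI 3, and 1 higher with 1 lower without sham 2.

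Of 30 gene lists tested in CA1, 6 were called by camera with a preset correlation between genes. The broadest was oxidative phosphorylation, the respiratory chain and ATP synthase, with 65 of 68 measured genes higher in TBI by a mean of 0.11 (camera adjusted p = 8.28e-11). Ndufb4 went from 73.6 ± 7.40 to 84.1 ± 1.82 FPKM (log2 0.20), Ndufa2 was higher by 0.21 and Atp5h by 0.16. Ribosomal protein genes were higher in 53 of 59, by a mean of 0.16 (camera adjusted p = 5.48e-09), among them Rps27 (33.6 to 44.4 FPKM, 0.41) and Rps23 (0.26). These genes have many processed copies, which makes their levels less certain. No member of either list passed adjusted over the list alone. Neither call held when the correlation was estimated (adjusted p = 0.801 with an estimated correlation, for both), and the exact permutation test of the list scores gave p = 0.171 and p = 0.114, where 0.0286 is the smallest p it can give. Without sham 3 the oxidative phosphorylation mean was 0.07, still called.

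The other 4 called lists were lower in TBI. Endothelial and pericyte markers were lower in 18 of 22 by a mean of -0.12 (camera adjusted p = 0.000967), and 2 passed adjusted over the list alone, the vascular growth factor receptors Flt1 (adjusted p = 0.0416) and Kdr (2.16 to 1.44 FPKM, log2 -0.47, adjusted p = 0.0470); the angiopoietin receptor Tek was lower by -0.25 without passing. Markers of pyramidal and excitatory neurons were lower in 15 of 18 by -0.12 (camera adjusted p = 0.00798), as in Rbfox3 (105 to 92.7 FPKM, -0.18), the CA1 marker Wfs1 (106 to 84.3, -0.33) and Mpped1 (-0.17). Voltage-gated ion channel genes were lower in 27 of 35 by -0.09 (camera adjusted p = 0.0241), with Kcnd2 at -0.21, Kcnab2 at -0.29 and Cacna1a at -0.24. Immediate early genes, which neurons switch on with activity, were lower in 17 of 25 by -0.11 (camera adjusted p = 0.0356), with Dusp6 (23.1 to 18.5 FPKM) at -0.31, Homer1 at -0.21 and Egr3 at -0.24. None of these calls held with an estimated correlation (adjusted p = 0.801 with an estimated correlation, for each), and the exact permutation p of their scores was 0.314, 0.114, 0.314 and 0.486.

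Each of these 4 calls was lost without at least 1 library. The endothelial call was lost without sham 1 (mean -0.04, adjusted p = 0.415), and also with a minimum mean of 5 FPKM (-0.07) or sample weights (-0.06), and the pyramidal call without TBI 2 (mean -0.08, adjusted p = 0.0997). The ion channel call was lost without sham 2 (-0.04), sham 3 (-0.05), TBI 2 (-0.08) or TBI 4 (-0.07), and its mean became -0.14 without sham 1. The immediate early call was lost without sham 1 (-0.09), sham 3 (-0.07), sham 4 (-0.06), TBI 1 (-0.07), TBI 3 (-0.07) or TBI 4 (-0.06), and its mean became -0.22 without sham 2 and -0.24 without TBI 2. It was also lost with sample weights and with samples of equal number as a block. Across 10077 CA1 genes, which are not independent replicates, fold changes were lower for genes of longer span (Spearman's rho -0.245). The median of the ion channel genes was -0.11, against -0.03 in random lists matched on span and FPKM. Without TBI 1 the number of lists called was 10.

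**Figure D1:**
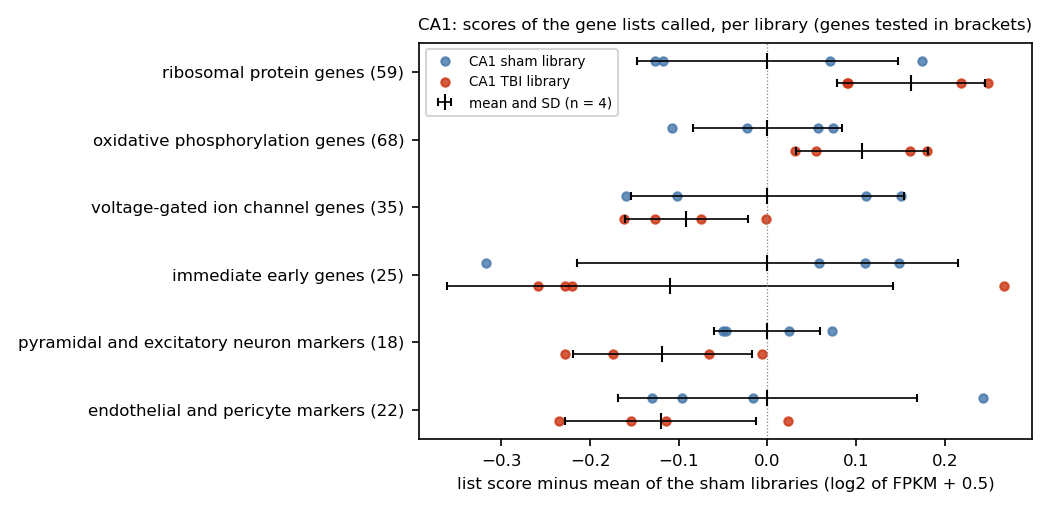
Score of each called gene list in each CA1 library, minus the mean of the sham libraries (log2 of FPKM + 0.5), with sham in blue and TBI in red; black ticks are group means, bars are SD, n = 4 libraries, and the number of genes tested stands in brackets. The mean gene of the oxidative phosphorylation list differed by 0.11 and that of the pyramidal list by -0.12, and sham and TBI libraries overlap in each list.

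Glial and inflammatory lists were not called in CA1. Microglia markers were higher in 13 and lower in 9 of 22 (mean 0.03, camera adjusted p = 0.229), and activated microglia genes split 10 and 10 (mean 0.05, adjusted p = 0.271). Astrocyte markers were higher in 10 and lower in 9 of 19 (mean -0.02, adjusted p = 0.810), and reactive astrocyte genes were higher in 9 of 15 (mean 0.06, adjusted p = 0.271). Complement genes were higher in 9 of 17 (adjusted p = 0.229), interferon-stimulated genes lower in 15 of 24 (adjusted p = 0.658) and oligodendrocyte markers lower in 15 of 27 (adjusted p = 0.842). Antigen presentation genes were higher in 10 of 15, with a mean of -0.01, a median of 0.11 and camera's direction up (adjusted p = 0.147). Of genes named in advance, the astrocyte filament Gfap stood at 343 ± 50.7 FPKM in sham and 293 ± 22.1 in TBI, Vim at 37.0 ± 5.01 and 44.0 ± 9.42, and the microglial Aif1 at 25.1 and 27.8. The lysosomal Cd68 stood at 0.983 and 1.24, complement C3 at 2.0 and 1.91, and myelin basic protein, Mbp, at 2772 ± 403 and 3334 ± 638. For neurons, the glutamate transporter Slc17a7 stood at 797 ± 76.1 and 747 ± 66.4 FPKM, Snap25 at 2846 ± 492 and 2502 ± 204, and the neurotrophin Bdnf at 12.3 ± 2.29 and 9.94 ± 1.48. None of these 9 passed (limma adjusted p = 0.891 to 0.978), and C3 lay between -0.22 and 0.13 when each library was left out.

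Choroid plexus markers, which come from tissue beside the hippocampus, varied between libraries of the same group. Transthyretin, Ttr, ran from 3.42 FPKM in sham 1 to 1271 in sham 2 and from 160 in TBI 2 to 2694 in TBI 1 (log2 1.75 ± 1.72 SE). The choroid plexus list was higher in 12 of 17 by a mean of 0.23 (camera adjusted p = 0.234), and the erythrocyte list, a measure of blood left in the tissue, was higher in 5 of 5 by 0.19 (adjusted p = 0.103). Markers of the dentate gyrus and CA3, the neighbouring fields, were lower in 12 of 18 (mean -0.04, adjusted p = 0.604).

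WBC, TBI against sham: which transcripts differ in the blood after the same injury. No row passed in limma among 13413 tested, although 2727 rows were at an unadjusted p under 0.05 (1049 higher, 1678 lower) where chance gives 671. The sham and TBI libraries did not overlap in 14.2% of rows, where chance gives 2.86%. The share of these 2727 that were higher, 38.5%, depended on the scaling: after quantile normalization 56.5% of such rows were higher. The genes with the smallest p, each with all 4 TBI libraries on one side of all 4 sham libraries, had limma adjusted p = 0.127. Lower in TBI were the proprotein convertase Furin (118 ± 4.93 to 65.7 ± 8.50 FPKM, log2 -0.85 ± 0.10 SE), Retsat (37.6 ± 3.87 to 22.8 ± 2.07, -0.71), the deubiquitinase Bap1 (71.1 to 38.2, -0.90), Ifrd2 (115 to 60.1, -0.94), the amino acid transporter Slc7a5 (33.1 to 17.4, -0.93), the GM3 synthase St3gal5 (113 to 73.9, -0.61), the Hippo pathway co-activator Wwtr1 (4.82 to 1.77, -1.22), the RNA helicase Ddx28 (-0.85), Hexim2 (-0.86) and Prss35 (4.09 to 0.762, -1.92). Higher in TBI were Slc14a1 (13.9 ± 4.68 to 28.1 ± 0.729 FPKM, 1.05), the row listed as Mir874 (0.77), KIFC2 (0.57), Rcbtb1 (0.53), Fkbp14 (0.50), the telomere-binding Terf1 (0.42), Prdm4 (0.37), the kinase Prpf4b (29.8 to 38.8, 0.37), the mitochondrial ribosomal gene Mrpl22 (11.4 to 14.7, 0.35) and the methionine adenosyltransferase Mat2a (0.31). Poly-A libraries read the transcript at the Mir874 locus, not the mature microRNA. Without TBI 2 limma called 1 row higher and 3 lower, Furin (-0.93) and Prss35 (-2.19) among the latter, and without sham 2 it called 1 higher.

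Transcripts of red cells and platelets were lower in the WBC of injured rats. All 22 erythroid and reticulocyte genes were lower, by a mean of -0.90 (camera adjusted p = 1.02e-09), and 16 of them passed adjusted over the list alone. Trim58 fell on that test from 85.4 ± 35.1 to 35.2 ± 10.7 FPKM (log2 -1.24), Gypc fell by 1.03 on the log2 scale and carbonic anhydrase, Ca2, went from 1305 ± 201 to 642 ± 222 (-1.08). Alas2, the first enzyme of heme synthesis in red cell precursors, stood at 9689 ± 2120 and 6080 ± 2044 FPKM (-0.72), without passing, and its groups overlap. Platelet and megakaryocyte markers were lower in 18 of 19 by a mean of -0.82 (camera adjusted p = 1.80e-06), 9 of them passing adjusted over the list alone. The platelet chemokine Ppbp went from 191 ± 16.5 to 56.9 ± 42.6 FPKM (-2.03), the receptor subunits Gp9 and Gp5 were lower by -1.36 and -0.91, and Pf4, which did not pass, stood at 6115 ± 855 and 3759 ± 1424 (-0.80). In each TBI library the erythroid score lay below every sham library, at -1.64, -0.52, -0.54 and -0.89 from the sham mean, and the platelet scores lay at -1.76, -0.69, -0.35 and -0.49. With an estimated correlation neither list was called (adjusted p = 0.592 with an estimated correlation for erythroid, 0.665 for platelet), the exact permutation test of each score gave its smallest p, 0.0286 (adjusted p = 0.133), and without TBI 1 the platelet mean was -0.51. For the WBC list erythroid and reticulocyte genes the mean was -0.59 after quantile normalization and -0.30 with rows of every status kept, where hemoglobin rows marked as having too many fragments are listed at 0, and both kept the call.

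Metabolic and cell division lists were also lower in the WBC of injured rats. Antioxidant and iron genes were lower in 24 of 24 by a mean of -0.53 (camera adjusted p = 1.52e-05), 5 of them passing adjusted over the list alone: the glutathione synthesis subunit Gclm went from 332 to 170 FPKM (-1.02), the iron exporter Slc40a1 was lower by -0.99 and biliverdin reductase, Blvrb, went from 154 to 76.7 (-1.07). Glycolysis genes were lower in 16 of 20 by -0.23 (camera adjusted p = 0.00287), with 6 lower and 1 higher (Hk2, 0.49) passing adjusted over the list alone; Slc16a1 was lower by -0.74, Aldoa by -0.52 (192 to 134 FPKM) and Ldha by -0.45, and quantile normalization brought the list mean to -0.13. Oxidative phosphorylation genes were lower in 58 of 67 by -0.21 (camera adjusted p = 2.50e-06), as in Ndufb11 (94.7 to 71.4 FPKM, -0.41), Ndufa12 (-0.88) and Cox8a (266 to 184, -0.54), and quantile normalization brought that mean to -0.01 and ended the call. Cell division genes were lower in 15 of 19 by -0.41 (camera adjusted p = 0.00865), with thymidylate synthase, Tyms (9.03 to 3.78 FPKM, -1.21), passing adjusted over the list alone, Mki67 at -1.47 and Rrm1 at -0.39, a call lost with a minimum mean of 5 FPKM. With an estimated correlation these 4 lists had p = 0.127, 0.114, 0.0890 and 0.237 (adjusted p = 0.592 with an estimated correlation for the antioxidant, glycolysis and oxidative phosphorylation lists, 0.665 for cell division), and the exact permutation p of the scores was 0.0286 for those 3 and 0.0571 for cell division. A fit with the erythroid score as a covariate, added after the data were seen, kept none of these 4 calls, nor that of the platelet list, and left 659 rows at an unadjusted p under 0.05, near the 671 that chance gives. That score separates sham from TBI completely, so the fit takes up most differences between the groups, and a call lost in it is not thereby tied to red cell RNA. Nor does the fit show these lists to be separate from red cell RNA. The antioxidant and iron list shares the gene Tfrc with the erythroid list.

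Among lists of leukocyte types, cytotoxic and natural killer cell markers were higher in TBI in 19 of 23 by 0.29 (camera adjusted p = 0.00134), with granzymes Gzmb at 2.56 and 4.55 FPKM (0.77) and Gzma at 36.2 and 52.2 (0.51), and Faslg at 0.46. That call was lost when the correlation was estimated (adjusted p = 0.665 with an estimated correlation), and the exact permutation test of the score gave p = 0.171. TBI 1 and TBI 4 lay 0.66 and 0.42 above the sham mean, while TBI 2 (0.03) and TBI 3 (0.05) lay within the sham range (up to 0.09). The mean was 0.17 without TBI 1, and it turned to -0.16 with the erythroid covariate. B cell markers were lower in 19 of 21 by -0.21 (camera adjusted p = 0.0401; adjusted p = 0.742 with an estimated correlation; exact permutation p = 0.40), with Fcrla at -0.38, Faim3 at -0.34 and Pou2af1 at -0.30; under quantile normalization the list mean was -0.01, without a call, and Faim3 turned to 0.04. The B cell call was lost without sham 2 (-0.21), sham 4 (-0.16), TBI 3 (-0.18) or TBI 4 (-0.04), with a minimum mean of 5 FPKM, with rows of 1 symbol only and with samples of equal number as a block. T cell markers were higher in 19 of 21 by 0.11 without passing (camera adjusted p = 0.0617). Neutrophil genes were lower in 11 of 17 (mean -0.16, adjusted p = 0.428) and monocyte markers in 12 of 20 (mean -0.06, adjusted p = 0.578).

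Interferon-stimulated genes were lower in 23 of 28 by -0.42 (camera adjusted p = 0.0328; adjusted p = 0.742 with an estimated correlation; exact permutation p = 0.143), as in Irf7 (486 ± 275 to 176 ± 76.4 FPKM, -1.38), Lgals3bp (-1.04) and the antiviral Rsad2 (1864 to 1003, -0.99). That call was lost without sham 2 (-0.29), sham 4 (-0.36), TBI 1 (-0.39), TBI 3 (-0.41) or TBI 4 (-0.32), after quantile normalization, with the erythroid covariate and with a minimum mean of 5 FPKM. Circadian clock genes were higher in 13 of 15 by 0.16 (camera adjusted p = 0.00865; adjusted p = 0.50 with an estimated correlation; exact permutation p = 0.0286), with Dbp (8.80 to 11.2 FPKM) at 0.33, Tef at 0.35 and Per2 at 0.27, and this was the only WBC list called by fry (adjusted p = 0.0167). That camera call was lost after quantile normalization (adjusted p = 0.085), with the erythroid covariate and with a minimum mean of 5 FPKM. Ribosomal protein genes were lower in 49 of 67 with a mean of -0.03 and a median of -0.11 (camera adjusted p = 0.0431; adjusted p = 0.742 with an estimated correlation; exact permutation p = 0.686), as in Rps2 (-0.37), Rpl6 (-0.16) and Rpl5 (-0.19). Under quantile normalization the ribosomal mean turned to 0.21 and Rpl5 to 0.20, and camera still called the list, there as higher in TBI. The call was lost without sham 1 (-0.04), sham 3 (-0.0034), sham 4 (-0.02), TBI 1 (0.0096) or TBI 2 (-0.01). The ribosomal mean was -0.07 without sham 2 and -0.08 without TBI 4. The call was also lost with a minimum of 5 FPKM, sample weights, the block, the erythroid covariate and rows of 1 symbol only.

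**Figure D2:**
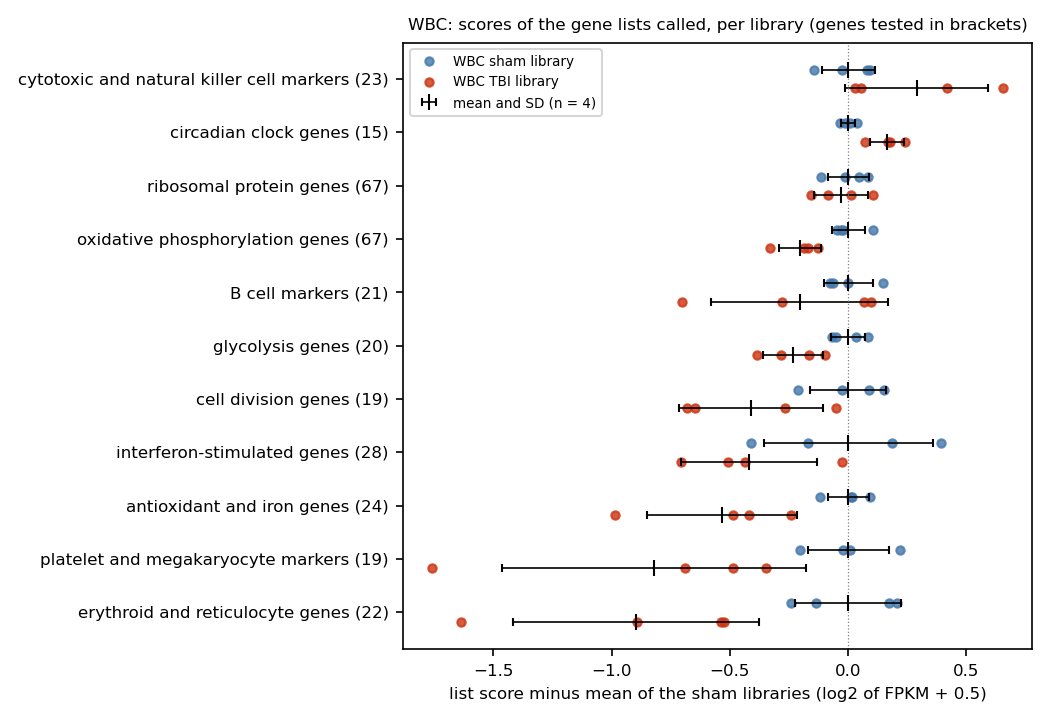
Score of each called gene list in each WBC library, minus the mean of the sham libraries (log2 of FPKM + 0.5), with sham in blue and TBI in red; black ticks are group means, bars are SD, n = 4 libraries, and the number of genes tested stands in brackets. The 4 TBI libraries lie at -1.64 to -0.52 on the erythroid list, all below the sham libraries.

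Lists of inflammation were not called in WBC. Genes of NF-kB and the inflammasome were lower in 13 of 21 (mean -0.07, camera adjusted p = 0.744), cytokines and chemokines in 8 of 11 (mean -0.17, adjusted p = 0.491) and adhesion and migration genes in 14 of 22 (mean -0.12, adjusted p = 0.138). Of genes named in advance, the neutrophil alarmin S100a8 stood at 338 ± 72.9 FPKM in sham and 257 ± 133 in TBI, the interleukin gene Il1b at 59.0 and 48.7, and the interferon-induced Isg15 at 57.4 ± 40.6 and 26.9 ± 16. For cell types, Cd3e of T cells stood at 125 and 126 FPKM, Cd79b of B cells at 381 ± 47.9 and 314 ± 79.7, Nkg7 of cytotoxic cells at 77.9 and 90.1, Csf3r of neutrophils at 14.5 and 13 and Cd14 of monocytes at 4.91 and 4.96. None of these passed, and the difference of Cd79b turned from -0.31 to 0.11 under quantile normalization.

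Between the tissues: does the effect of TBI differ between CA1 and WBC. The interaction term of limma, over 7570 genes measured in both, passed for 4 genes with a higher and 27 with a lower effect in WBC. The urea transporter Slc14a1 went opposite ways, lower in CA1 and higher in WBC, each with fully separated groups (WBC minus CA1 1.45 ± 0.23 SE, adjusted p = 0.0146). Lower effects in WBC had Wwtr1 (-1.25 ± 0.18), Ifrd2 (-1.22 ± 0.18), Hexim2 (-1.08 ± 0.17), Ddx28 (-0.80 ± 0.12) and Furin (-0.77 ± 0.11), all at an adjusted p of 0.0143. The CA1 differences of these 5 genes lay between -0.08 and 0.28. Higher effects in WBC had the semaphorin Sema7a (0.81 ± 0.16, adjusted p = 0.0381), the Mir874 row (0.87 ± 0.17, adjusted p = 0.0381) and Etv3 (0.45 ± 0.09, adjusted p = 0.0432), while the GABA receptor Gabbr1 (0.69) did not pass (adjusted p = 0.0593).

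How many genes passed depended on single libraries. The count of 31 became 7, 10 and 10 without CA1 sham 2, 3 or 4, and 13, 12, 7 and 6 without CA1 TBI 1, 2, 3 or 4. It became 7, 46 and 48 without WBC sham 2, 1 or 4, and 94, 167, 222 and 9 without WBC TBI 1, 2, 3 or 4. Slc14a1, Wwtr1, Furin, Ifrd2, Hexim2 and Ddx28 kept their calls without any of the 16 libraries. Sema7a and Mir874 each lost theirs without 10 of them and Etv3 without 11. With the samples of equal number in the tissues treated as 1 rat, limma called 3 genes, and none of those named here passed (adjusted p = 0.0756 to 0.10).

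Of 14 gene lists compared between the tissues, a test added after the data were seen, camera called 4, all lower in WBC. Oxidative phosphorylation genes differed by -0.31 (camera adjusted p = 4.00e-11), being higher in CA1 and lower in WBC. A permutation test of the score gave an adjusted p of 0.0343, but it regrouped each tissue on its own, as if the tissues came from different rats. By that permutation test the other 3 lists did not pass, with an adjusted p of 0.0610 for antioxidant and iron, 0.121 for glycolysis and 0.130 for ribosomal protein genes. Ribosomal protein genes differed by -0.26 (camera adjusted p = 4.36e-06), antioxidant and iron genes by -0.54 (camera adjusted p = 7.04e-05) and glycolysis genes by -0.24 (camera adjusted p = 0.00526). None of the 4 was called when the correlation was estimated (adjusted p = 0.439 with an estimated correlation, for each). Quantile normalization ended the calls of glycolysis (-0.11, adjusted p = 0.0675) and ribosomal protein genes (0.03, adjusted p = 0.844) and brought oxidative phosphorylation to -0.09 and antioxidant and iron genes to -0.35, both still called. With no filter on low values the ribosomal difference was -0.16.

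Across the 7570 genes no relation in size was detected between the fold changes of the tissues: Pearson's r was 0.032 (permutation p = 0.57) and Spearman's rho -0.00376 (permutation p = 0.95). Genes are not independent replicates, and these p-values come from 100 drawn regroupings of the libraries, the real one included. Regrouped libraries gave r from -0.20 to 0.16, so a relation within that range could not be told from chance. An overlap of calls could not arise, since limma called 0 of these genes in CA1 and 0 in WBC. At an unadjusted p under 0.05 in both tissues, 42 genes had the same direction, against 33.4 if the tissues were unrelated. In 27 genes the libraries separated the same way in both tissues and in 9 the opposite way, where unrelated directions would give 18.5 and 17.0, given the 221 CA1 and 1216 WBC genes that separated. Retsat was lower by -1.03 in CA1 and -0.71 in WBC, the transglutaminase Tgm2 by -0.68 and -0.95, and Akt2 by -0.34 and -0.54. Dbp was higher in both, by 0.56 and 0.33.

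**Figure D3:**
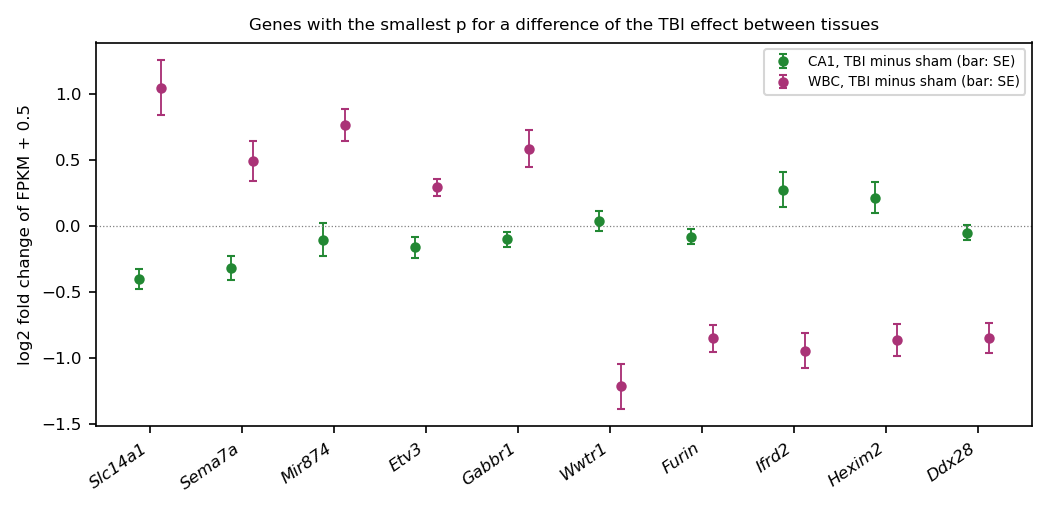
Effect of TBI (log2 fold change against sham, points, with SE as bars, n = 4 libraries per group) in CA1 (green) and WBC (purple) for the 10 genes named from the test between tissues. Slc14a1 lies at -0.40 in CA1 and 1.05 in WBC, and Furin at -0.08 and -0.85.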

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

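The comparison of gene lists between the tissues was chosen after results were seen. Groups of 4 libraries were searched for a library far from the other 3, which chance gives in about 1 of 20 groups. It was found in 13 of 252 groups, where chance gives about 13.

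In CA1, Git1 stood at 198 FPKM in sham 4 against 181 to 183 in the other sham libraries. Kcnab2 stood at 253 in sham 1 against 368 to 392, and Dusp6 at 20.3 in sham 1 against 23.7 to 24.2. TBI 4 had Dusp6 at 16.7 FPKM against 18.9 to 19.3 and Vim at 58.1 against 37.8 to 40.5. TBI 2 had an immediate early score of 4.16 (log2) against 3.63 to 3.67 in the other TBI libraries.

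In WBC, sham 2 had Rsad2 at 2537 FPKM against 1599 to 1674 and Csf3r at 26.1 against 10.4 to 10.8. Rps2 stood at 78.4 in sham 4 against 98.8 to 103, and the oxidative phosphorylation score at 6.0 (log2) in sham 3 against 5.85 to 5.88. TBI 1 had Prdm4 at 9.94 FPKM against 9.15 to 9.26, Blvrb at 36.3 against 87.0 to 95.7 and Rps2 at 64.7 against 75.2 to 76.9.

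The effect of TBI differed between the tissues by the unpaired interaction test for 9 named genes. None of the 9 passed with samples of equal number in the tissues treated as 1 rat (limma adjusted p = 0.0756 to 0.10). WBC minus CA1, on the log2 scale, the effect of TBI was 1.45 for Slc14a1, 0.81 for Sema7a, 0.87 for Mir874 and 0.45 for Etv3. It was -1.25 for Wwtr1, -1.22 for Ifrd2, -1.08 for Hexim2, -0.80 for Ddx28 and -0.77 for Furin. Among gene lists it was -0.54 for antioxidant and iron genes, -0.31 for oxidative phosphorylation, -0.26 for ribosomal proteins and -0.24 for glycolysis. None of the 4 was called when the correlation was estimated (adjusted p = 0.439 with an estimated correlation), and by the permutation test, which did not pair the tissues, only oxidative phosphorylation passed (adjusted p = 0.0343).

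Hbb-b1, a hemoglobin beta gene, was left out of the tests because its status in the 4 WBC sham libraries reads as too many fragments to process, with the value listed at 0. That 0 does not mean absence. In the TBI libraries it had values of 2496, 3910, 5222 and 3755 FPKM.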

How the results depend on the processing

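Chosen after the data were seen were the settings with rows of every status, rows with 1 symbol and the erythroid covariate, and the results on unadjusted p and on lists between tissues. List values between tissues kept direction and call in 64 of 64 cases when a library was left out. They did so in 38 of 40 under other settings, both losses under quantile normalization. These 40 leave out camera with an estimated correlation, which called 0 lists between tissues. Where a value below moved, the cause was not tested, except that a filter changes how many rows are tested. Unknown depth keeps counting error out of every value here.

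In CA1 (1 higher, 0 lower, 752 at an unadjusted p under 0.05, 6 lists), the count at an unadjusted p was 1256 with no filter, 450 with a minimum mean of 5 FPKM and 2022 with sample weights. Quantile normalization, no trend, weights, rows with 1 symbol and an adjusted p of 0.1 each gave 1 lower, and no trend, weights and 0.1 gave 2 higher. Rows with 1 symbol, where the unnamed locus is left out, gave 1 higher. Genes named for CA1 gained a call in 7 cases under settings other than leaving out a library. Camera with an estimated correlation called 0 lists and fry 0. In WBC (0 called, 2727, 11 lists), 2 rows were higher with every status kept and 1 at 0.1. The lists called were 7 at the minimum of 5, 4 with the erythroid covariate, 0 with an estimated correlation and 1 by fry, and the covariate left 659 rows at an unadjusted p under 0.05. Between tissues (31 genes, 4 lists) there were 13 genes with no filter, 20 at the minimum of 5, 281 with weights, 214 with sham and TBI of equal number as a block and 3 with CA1 and WBC of equal number as a block; lists were 0 with an estimated correlation.

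Directions turned as follows (log2). Quantile normalization gave Faim3 0.043, Rpl5 0.20, Cd79b 0.11 and the WBC ribosomal list 0.205. That list stayed called there, in the opposite direction. Weights gave Csf3r 0.11 and Nkg7 -0.049. The erythroid covariate gave Mki67 0.011, Rsad2 0.10, S100a8 0.13, Csf3r 0.90, Nkg7 -0.74, Pf4 0.15, Alas2 0.29, Il1b 0.59, the cytotoxic list -0.16, the platelet list 0.042 and the ribosomal list 0.040.

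Leaving out each library gave, in CA1, 1 to 2 higher, 0 to 1 lower, 493 to 1802 at an unadjusted p under 0.05 and 5 to 10 lists. In WBC it gave 0 to 1 higher, 0 to 3 lower, 2195 to 2733 and 9 to 12 lists, and between tissues 6 to 222 genes and 4 to 6 lists. The fold-change correlation ran from 0.008 to 0.050. Calls shared by the tissues stayed at 0, which was fixed, since the tissue with all its libraries had no called gene among those compared. Ranges that cross 0 were the WBC ribosomal list -0.077 to 0.0096, C3 -0.22 to 0.13, Ttr -0.059 to 2.72, Cd14 -0.27 to 0.36, Cd3e -0.10 to 0.12, Csf3r -0.28 to 0.20 and Nkg7 -0.13 to 0.27.

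Of the CA1 list values, 36 kept their direction and call when a library was left out and 12 lost the call, and 62 and 16 did under other settings. For WBC lists these were 74 and 14, then 108 and 42, with 4 turned. Blocking sham and TBI of equal number gave CA1 869 rows at an unadjusted p under 0.05 and 5 lists, and WBC 2634 and 10; the immediate early, B cell and WBC ribosomal calls were lost. Deviations of equal numbers correlated in CA1 at 0.21, 0.02, 0.05 and 0.24, and not every sample matched its own number best, so the numbers were not taken as pairs. Robust variances were not run for camera, nor trend, robust variances and blocks for the correlation.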

Other observations

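The tests of WBC TBI 1 alone, of the reach of the erythroid test, of the spread of the oxidative phosphorylation score, of the share of genes going the same way in both tissues and of libraries from the same rat were chosen after the results were seen, as were the genes named in this part.

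Clock genes of CA1 stood on both sides of 0, which the list mean hides. Over the circadian list, limma's fry test for change in either direction gave a mixed p of 2.08e-05. Camera, which asks for one direction, did not call the list (9 of 17 higher, mean 0.07, adjusted p = 0.0747). Adjusted over the list alone, 4 genes were higher in TBI, which were RGD1566380 (a synonym of Ciart, a clock repressor; 0.40), Dbp (0.56), Per3 (0.25) and Nr1d2 (0.21), and Nfil3, which opposes Dbp at its binding sites, was lower (-0.32). None of the 5 passed over all rows (limma adjusted p = 0.710 to 0.891). In WBC the same genes stood at 0.38, 0.33, 0.26, 0.19 and -0.35, none of them passing there. The hour at which tissue was taken is not given in the sources used here.

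The matrix and wound genes of CA1 split 11 and 11 and were not called as a list (camera adjusted p = 0.274). Adjusted over the list alone, the protease inhibitor Timp1 (0.53) and the proteoglycan decorin, Dcn (0.36), were higher in TBI, and the membrane protease Mmp14 (-0.52) was lower, and none of the 3 passed over all rows (limma adjusted p = 0.891). Timp1 also passed within the reactive astrocyte list (adjusted p = 0.0415), although Gfap stood lower by -0.22 without passing.

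Splits of the libraries that ignore the surgery gave the following. In CA1, 11 of the 35 splits called at least as many rows as the 1 called (highest other 1), 12 gave at least the 752 rows at an unadjusted p under 0.05 (highest other 1793) and 25 called at least 6 lists (highest other 17), so chance is not excluded for these counts. A count does not weigh how far the called row, XLOC_003441, lies beyond its spread (0 to 0.00348 FPKM in sham, 9.11 to 10.8 in TBI). In WBC, 1 of 35 splits, the real one, gave 2727 rows at an unadjusted p under 0.05 (highest other 1349). That is the smallest share that 35 splits can give. It makes chance unlikely for that excess at 0.05, without adjustment for the other counts put to this test. All 35 splits gave at least the 0 rows called (highest other 2), and 8 called at least 11 lists (highest other 19), so chance is not excluded for the number of lists. For genes that differ between the tissues, 3 of 100 drawn regroupings, the real one included, gave at least 31 (highest other 194). That makes chance unlikely at 0.05 for the unpaired model alone, since only 3 genes were called with samples of equal number as 1 rat. Each tissue was regrouped on its own, and a draw could keep the real groups of 1 tissue. The regrouping with 194 genes therefore cannot be tied to a structure of the samples apart from the surgery, and what set it was not tested.

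Lower erythroid and platelet transcripts in WBC after TBI do not rest on 1 library. Without WBC TBI 1, the lowest, the erythroid score still differed by -0.651, and the other 3 TBI libraries lay below all 4 sham libraries. A smaller share of red cell RNA in the TBI libraries may account for the erythroid part and stays open: once the list mean of each library was taken off, 0% of the 22 members differed, but the test had the reach to pass a difference of 0.45, which is 50% of the list mean, in 0 of them. Their fold changes ran from -1.24 to -0.35. Whether that share was set in the blood after injury or while white cells were separated was not tested.

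The rise of oxidative phosphorylation and ribosomal protein transcripts in CA1 after TBI exceeded that of lists matched on gene span and level. Fold changes did fall with gene span (Spearman's rho -0.245 across 10077 genes). Yet the median of the oxidative phosphorylation list, 0.0996, lay at percentile 100 of 10000 lists matched on span and FPKM. Medians of these lists centred on 0.0202 (95% of them between -0.00362 and 0.0484). Matched lists were drawn gene by gene, so their range leaves out the correlation between list members (estimated at 0.298). That percentile may thus overstate how far the list lies from what span and level give. Spread between libraries of the same group stays open as a possible explanation, since 6 of the 35 splits gave a score difference at least as large as the real 0.107 (highest other 0.129). A response of CA1 cells to injury was not tested apart from it. Against its own matched lists the ribosomal list also lay at percentile 100 (median 0.152). The called lists that were lower in TBI lay at percentiles 0 to 0.07. Among them was the immediate early list, whose score had an exact permutation p of 0.486. An extreme percentile was thus not particular to the lists that rose.

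Genes shifted the same way in both tissues, such as Retsat, Akt2, Tgm2 and Dbp, none of which passed over all rows in either tissue, were not shown to exceed what differences between rats give. With equal numbers read as 1 rat, the real split separated 27 genes the same way in CA1 and WBC (highest other split 19), but that count rises with the genes separated in WBC alone, 1216 against at most 388 in another split. Of the genes separated in both tissues 75% went the same way, as did at least as large a share in 4 of the 6 splits with at least 10 such genes, the real one included (highest other 76.9%), too few splits for a share under 0.05. The excess of same-way genes over unrelated directions was 8.52, against up to 8.72 in another split, so differences between rats that are unrelated to the surgery stay open.

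Whether equal numbers are 1 rat was tested over 99 variable genes: among all ways to match CA1 to WBC libraries within the groups, equal numbers ranked 1 (mean r 0.274, next 0.266), and 6 of 8 libraries matched their own number best. Libraries of equal number may thus come from the same rat, but this match does not settle it. In CA1, sham and TBI libraries of equal number, which are different rats, correlated in their deviations at 0.21, 0.02, 0.05 and 0.24.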
